A study of Mus musculus with 16 samples.

How the data were processed

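Gene expression was measured on Affymetrix Mouse430_2 arrays in 16 samples of mouse embryonic gonad, in 8 groups of 2 by genotype (wild type or Wnt4 knock-out), sex and stage (E12.5 or E14.5). Per the labels' protocols, total RNA was purified on columns, 8 ug per sample went into labelling, gonads stayed frozen until PCR had given the genotype, and stages were read from morphology. Titles of the male samples name an ovary while their source names testis, and these samples were treated as testis.

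The deposited values are probe-set intensities on a linear scale for 45101 probe sets. MAS5 is the only tool named, per the submitters' processing notes, and its version, its scaling target and any further step are not given in the sources used here. The highest and lowest 2% trimmed mean of an array differed by 1.06-fold, below the limit of 1.5 fixed before the data were examined, so the deposited scale was kept.

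Intensities were turned into log2(intensity + 4), where 4 is the rounded median over arrays of the 20th percentile. The 64 control probe sets were left out of the gene tests. Probe sets above the array median in at least 2 arrays were kept, 25620 in all. Gene names came from the platform annotation of 2016, with symbols updated through Entrez numbers for the 34754 that were found. In it 34945 probe sets had 1 symbol, 932 had several and were not named, and 9160 had none here. Each gene was represented by its probe set with the highest mean, which gave 12336 genes, and since other probe sets of a gene can disagree their mean was an alternative. Values of all arrays were fitted together with a mean per group in limma 3.58.1 (R 4.3.3), with moderated variances that follow an intensity trend (8 residual and 5.29 prior degrees of freedom). All tests were two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.050. The 12 contrasts were knock-out against wild type in each sex and stage, testis against ovary and E14.5 against E12.5 in wild type, and the 4 interactions.

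At the same early point 20 gene lists were fixed, for pre-granulosa cells, WNT/beta-catenin feedback targets, Sertoli cells, fetal Leydig cells and steroidogenesis, adrenal cortex, chromaffin cells and sympathetic neurons, cholesterol synthesis, endothelium, arterial endothelium, germ cells of either sex, meiosis, male germ cell differentiation, interstitium, surface epithelium, mesonephros and genital ducts, erythroid cells, macrophages, proliferation, p53 targets, and immediate early and heat shock genes. Of their 276 members 243 were tested. Lists were tested with camera at a preset correlation of 0.010, adjusted over the lists of a comparison, with an estimated correlation and with fry as alternatives. A shift toward the other sex was tested with fry on the sex difference of the other stage. Named genes followed a rule fixed with the lists: Wnt4 and the sex-linked genes, then per comparison the 10 largest rises and the 10 largest falls among genes past the threshold whose arrays did not overlap between the groups, and up to 4 members per list by smallest p.

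The share of opposite-sex RNA was estimated from Eif2s3y, Kdm5d and Uty in ovary arrays and from Xist in testis arrays, relative to arrays of the other sex at the same stage. Alternatives fixed with the lists covered the pseudocount, the filter, the normalization, the variance model, array weights, the replicate number as a block, the probe set summary, the thresholds, the lists and leaving out each array. Covariates for opposite-sex RNA and the 3'/5' ratio, averaging of the almost identical arrays, leaving out E12.5 arrays with a 3'/5' log2 ratio above 0.50 and E14.5 arrays with more than 10% opposite-sex RNA, and a crossed pairing were added after the data had been seen. The code was tested on simulated data for the 12336 genes, and rates in the real arrays were not measured. Of 100 genes changed 2-fold and 100 changed 4-fold, 45 and 95 were recovered in knock-out ovary E12.5, and 44 and 81 at E14.5. In knock-out testis these were 42 and 94 at E12.5, and 41 and 94 at E14.5. In that order 9, 6, 12 and 6 unchanged genes were called, 6.04%, 4.58%, 8.11% and 4.26% of the calls. Figures were drawn in Python 3.11.15. Genome coordinates were not used here.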

Results

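Gonads were taken from mouse embryos of both sexes at embryonic days 12.5 (E12.5) and 14.5 (E14.5), from wild-type animals and from animals with a knock-out of Wnt4, which encodes a secreted signalling protein of the WNT family with a known part in ovary development. RNA was hybridised to 16 Affymetrix mouse arrays, 2 for each of the 8 combinations of genotype, sex and stage. The labels call the arrays of a group biological replicates but do not say whether an array held a single embryo or a pool, so p-values measure only the spread between these arrays. Mean deposited intensity lay between 272 and 288 per array, and 12336 genes were tested. The number of arrays limits the precision of each comparison. Fold changes are on the scale of log2(intensity + 4), which understates the change of genes with low intensity. Medians of gene lists are log2 changes. Group values are mean intensities ± SD of n = 2 arrays.

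Wnt4 itself was read first. In the ovary at E14.5 it fell from 1144 ± 8.92 to 327 ± 34.8, a log2 change of -1.80 (SE 0.358, limma adjusted p = 0.0445). That call was lost when any of the 4 arrays was left out, with log2 changes of -1.81 without wild-type replicate 1, -1.79 without wild-type replicate 2, -1.91 without knock-out replicate 1 and -1.69 without knock-out replicate 2. At E12.5 the ovary arrays labelled Wnt4 knock-out read 839 and 520.2 against 844 and 1822 in wild type, a log2 change of -0.90 that did not pass the test (adjusted p = 0.523). In the testis Wnt4 read 413 and 231 against 502 and 473 at E12.5 and 277 and 371 against 753 and 512 at E14.5 (knock-out against wild type), with adjusted p of 0.528 and 1.0. A second Wnt4 probe set read 441 and 193 in knock-out against 392 and 759 in wild-type ovaries at E12.5, and 101 and 102 against 513 and 423 at E14.5. In testis it read 183 and 90.6 against 189 and 238, and then 98.8 and 106 against 272 and 165. Ovary E12.5 replicate 1 labelled knock-out thus lay close to wild-type replicate 1 in one set and above it in the other. The deleted part of Wnt4 and the position of the probe sets relative to it are not given in the sources used here, so the remaining signal does not check the genotype labels.

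Sex labels were checked with Xist, the transcript that silences an X chromosome in females, and with the Y-linked genes Eif2s3y, Kdm5d and Uty. Ddx3y, another Y-linked gene, is not named in the annotation used here. Xist read 3654 to 5805 in the ovary arrays and 5.92 to 1087 in the testis arrays. Eif2s3y read 856 to 1350.3 in testis and 3.67 to 245 in ovary, and Kdm5d and Uty reached 78.7 and 19.9 in ovary arrays against at least 249 and 90.5 in testis arrays. The Y-linked signal corresponded to 21.7% and 7.97% testis RNA in the wild-type ovary arrays at E12.5, to 18.7% in knock-out ovary E12.5 replicate 2 and to 19% in wild-type ovary E14.5 replicate 2. Xist corresponded to 22.8% ovary RNA in wild-type testis E14.5 replicate 2 and to 16.5% in knock-out testis E14.5 replicate 2. The 3'/5' signal ratio of actin and Gapdh control probe sets, which increases when labelled RNA is short, was 2.27 in knock-out ovary E12.5 replicate 1, 1.76 in wild-type ovary E12.5 replicate 2 and 1.76 in knock-out testis E12.5 replicate 1. The wild-type testis arrays at E12.5 were almost identical. The SD of their log2 difference over genes was 0.142, against 0.335 to 0.587 in the other pairs. Where their mean as 1 array moves a gene count by over 1.5 times, that count stands beside it. The sources used here do not say whether both hold the same RNA, and so are 1 sample. If so, their SD and, as groups share a variance per gene, every p-value partly reflect technical spread.

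**Figure D1:**
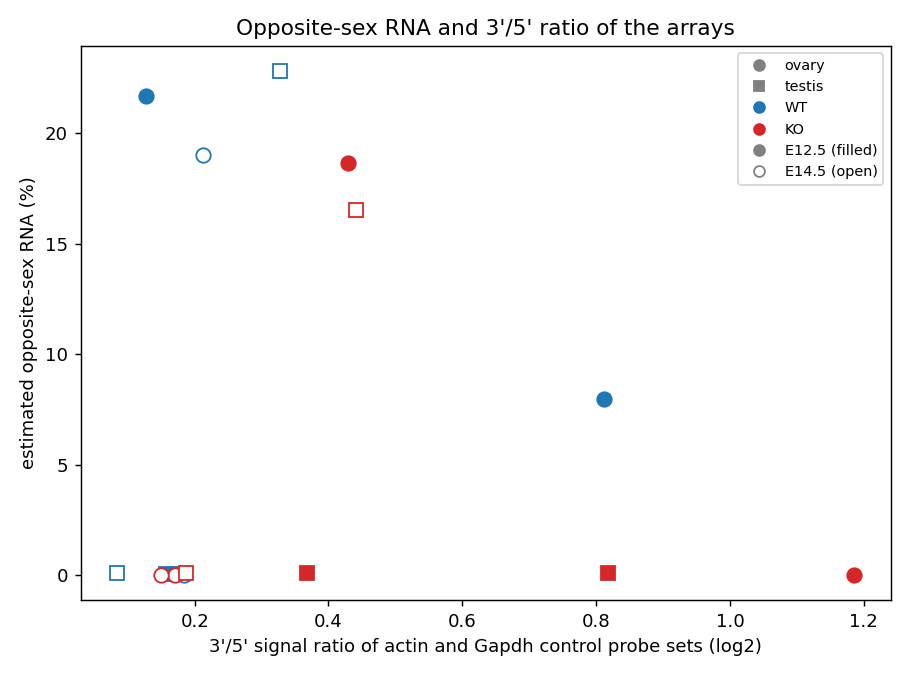
Estimated share of RNA from the opposite sex (vertical axis, percent) against the 3'/5' signal ratio of actin and Gapdh control probe sets (horizontal axis, log2) for each of the 16 arrays, with circles for ovary, squares for testis, blue for wild type, red for knock-out, filled symbols for E12.5 and open symbols for E14.5. Knock-out ovary E12.5 replicate 1 lies farthest right at 1.18, and wild-type testis E14.5 replicate 2 lies highest at 22.8%.

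The first comparison asked which ovarian genes differ between the arrays labelled Wnt4 knock-out and wild type at E12.5. Genes of the supporting cells of the fetal ovary were lower. Fst, which encodes the activin antagonist follistatin, fell from 724 ± 50.6 to 68.4 ± 18.3 (10.2-fold, log2 change -3.35, SE 0.54). The homeobox gene Msx1 fell from 217 ± 40.6 to 33.5 ± 3.95 (5.87-fold), and Phlda2, an imprinted gene, fell from 122 ± 34 to 7.09 ± 2.4 (11.3-fold). Notum, which encodes a secreted enzyme that inactivates WNT proteins, fell 6.31-fold, and Lgr5, a receptor gene for R-spondins, fell 2.79-fold. Osr2 (4.92-fold), Insyn2b (6.88-fold), Sorbs2 (3.31-fold), Dach2 (3.2-fold) and Igfbp2 (2.61-fold) fell as well.

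Of 15 measured pre-granulosa genes, the supporting cells of the fetal ovary, 3 fell (Fst, Msx1 and Lgr5) and 12 did not pass. In that list 10 fell when adjusted over the list alone (median -0.99, camera adjusted p = 2.85e-12, adjusted p = 0.0362 with an estimated correlation). Irx3, a member that did not pass, read 84.7 ± 3.6 against 803 ± 353 (adjusted p = 0.0552). Of 15 genes in the WNT/beta-catenin feedback list, 2 fell (Notum and Lgr5) and 13 did not pass. In that list 6 fell when adjusted over the list alone (median -0.44, camera adjusted p = 7.2e-10, adjusted p = 0.0599 with an estimated correlation). Tnfrsf19 in that list read 259.7 ± 20.1 against 1277 ± 435 (adjusted p = 0.0589). The pre-granulosa and WNT lists share 2 genes, Lgr5 and Lef1. Both lists kept their camera call on leaving out any single array. Testis RNA was 21.7% and 7.97% in the wild-type arrays and 0% and 18.7% in those labelled knock-out.

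Genes that rose in the ovary arrays labelled knock-out at E12.5 included several neuronal and striated muscle genes. Tissue dissected along was not tested as their source. Tacr3, the neurokinin B receptor gene, rose from 18.4 ± 8.03 to 166 ± 56.7 (7.63-fold, log2 change 2.93, SE 0.54), and the striated muscle genes Myh3 and Tnnc1 rose 6.71-fold and 5.77-fold. Plbd1 (6.72-fold), the elastase gene Cela3b (6.57-fold), Ccdc182 (5.74-fold), the protocadherin gene Pcdh8 (5.37-fold), the thrombomodulin gene Thbd (5.2-fold) and the neuronal genes Stmn3 (5.49-fold) and Scn3b (5.11-fold) also rose. Th, which encodes the rate-limiting enzyme of catecholamine synthesis, rose from 14.7 ± 1.6 to 94.4 ± 45.7 (4.99-fold). Lefty2, an antagonist of Nodal signalling, rose 3.45-fold. Some folds moved by over 1.5 times without knock-out replicate 1 or knock-out replicate 2. In order, these were 10.8 and 4.19 for Myh3, 9.73 and 3.42 for Tnnc1, 3.76 and 8.77 for Ccdc182 and 2.87 and 10.5 for Stmn3.

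Of 11 chromaffin and sympathetic neuron genes, 1 (Th) rose. In that list 4 rose when adjusted over the list alone (median 0.78, camera adjusted p = 1.14e-07, adjusted p = 0.168 with an estimated correlation). In the fetal Leydig and steroidogenesis list, 0 of 9 genes passed limma, with 5 at an unadjusted p under 0.05. In that list 3 rose when adjusted over the list alone (median 0.75, camera adjusted p = 8.65e-05, adjusted p = 0.41 with an estimated correlation). Hsd3b1, a steroid dehydrogenase gene, read 416 ± 163 against 71.5 ± 16.9 there (adjusted p = 0.183). In the adrenal cortex list, 0 of 8 passed limma, 5 had an unadjusted p under 0.05 and 4 rose when adjusted over the list alone (median 0.79, camera adjusted p = 3.62e-06, adjusted p = 0.124 with an estimated correlation), with Cyp11b1, an adrenal steroid hydroxylase gene, at 74.5 ± 54.1 against 14.7 ± 1.75 (adjusted p = 0.0934). Of 8 male germ cell genes, 1 (Lefty2) rose. In that list 3 rose when adjusted over the list alone (median 0.0982, camera adjusted p = 0.0305, adjusted p = 0.429 with an estimated correlation). The macrophage list had 0 of 12 and the endothelial list 0 of 16 genes past limma, with 2 and 1 at an unadjusted p under 0.05, and 0 and 0 rose when adjusted over the list alone. Their camera results were, for macrophages, median 0.52, camera adjusted p = 0.000768, adjusted p = 0.398 with an estimated correlation, and for endothelium, median 0.32, camera adjusted p = 0.0496, adjusted p = 0.601 with an estimated correlation. Knock-out replicate 1 had a 3'/5' ratio of 2.27, and the fetal Leydig median relative to wild type was 1.45 in that array and 0.42 in replicate 2. Camera calls were lost (medians in parentheses) for the chromaffin list without wild-type replicate 2 (0.61), the endothelial list without wild-type replicate 1 (0.0827), wild-type replicate 2 (0.54), knock-out replicate 1 (0.0922) and knock-out replicate 2 (0.56), the male germ cell list without wild-type replicate 2 (0.18) and knock-out replicate 2 (0.18) and the macrophage list without knock-out replicate 1 (0.19). On the fold scale medians moved by over 1.5 times, with the call kept, for the fetal Leydig list (1.89 without wild-type replicate 2 and 1.45 without knock-out replicate 2) and for the chromaffin list, to 1.60 without wild-type replicate 1.

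In total 36 genes changed in the ovary at E12.5, 23 higher and 13 lower (limma, Benjamini-Hochberg adjusted), and 989 had an unadjusted p under 0.05. The count was 16 without wild-type replicate 2, 19 without knock-out replicate 1 and 203 without knock-out replicate 2. It was 9 with the almost identical wild-type testis arrays averaged, 12 without wild-type replicate 2 and knock-out replicate 1, the arrays of high 3'/5' ratio, 7 with the stricter filter, 0 with only the 4 arrays of the comparison, and 58 with the opposite-sex share as a covariate. Of 22 named genes past the threshold, 10, 14, 12 and 2 lost it without wild-type replicate 1, wild-type replicate 2, knock-out replicate 1 and knock-out replicate 2, in that order.

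At E14.5 the same question was put to ovaries of a later stage, when wild-type ovaries expressed meiotic genes. WNT targets and supporting-cell genes fell in the knock-out. Notum fell from 146 ± 0.899 to 12.4 ± 2.73 (9.22-fold, log2 change -3.21, SE 0.455), Lgr5 fell from 115 ± 35.7 to 17.3 ± 1.73 (5.46-fold), and the Iroquois homeobox gene Irx5 fell 5.88-fold. Calb1, which encodes the calcium-binding protein calbindin, fell from 311 ± 66.3 to 22.2 ± 0.437 (11.9-fold), and the zinc finger gene Sall1 fell 12.5-fold. Insyn2b (8.68-fold), Tmem132c (5.2-fold), Lypd6b (5.08-fold), Smpx (4.9-fold) and Dach2 (4.74-fold) fell as well. Folds moved by over 1.5 times without wild-type replicate 1 or 2 for Insyn2b (5.53 and 13.6) and Smpx (3.21 and 7.48). They did so without knock-out replicate 1 or 2 for Tmem132c (3.46 and 7.82).

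Of 15 pre-granulosa genes at E14.5, 4 fell, namely Irx5, Lgr5, Msx1 (3.07-fold) and the transcription factor gene Runx1 (2.78-fold), and 11 did not pass. Adjusted over the list alone, 8 fell and 1 rose (median -1.44, camera adjusted p = 3.47e-13, adjusted p = 0.029 with an estimated correlation). Of 15 WNT feedback genes, 3 fell (Notum, Lgr5 and Nkd2, 2.94-fold). In that list 9 fell when adjusted over the list alone (median -1.04, camera adjusted p = 3.33e-12, adjusted p = 0.0325 with an estimated correlation). Of 8 mesonephros and genital duct genes, 2 fell (Calb1 and Pax8, 2.07-fold). In that list 3 fell when adjusted over the list alone (median -0.65, camera adjusted p = 2.91e-05, adjusted p = 0.148 with an estimated correlation). These 3 lists kept their camera call on leaving out any single array, and wild-type replicate 2 held 19% testis RNA.

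Cpa1, a carboxypeptidase gene, rose from 67 ± 19.3 to 679 ± 147 (9.69-fold, log2 change 3.28, SE 0.357) in the knock-out ovary at E14.5. The serotonin receptor gene Htr1b (6.14-fold), the matrix protein gene Aspn (6.04-fold), the chondromodulin gene Cnmd (6.0-fold), Rtl3 (5.33-fold), Fmo2 (4.98-fold), Thbd (4.4-fold), Rassf2 (3.77-fold) and Ramp1 (3.57-fold) rose too. Of 8 male germ cell genes, 2 rose, the Nodal antagonists Lefty1 (4.23-fold) and Lefty2 (3.17-fold). For male germ cell genes this was also 2 adjusted over the list alone (median 0.0536, camera adjusted p = 0.00648, adjusted p = 0.419 with an estimated correlation). In each of the interstitial, adrenal cortex, chromaffin, cholesterol synthesis and germ cell lists, 0 genes passed limma, with 1, 1, 1, 0 and 2 at an unadjusted p under 0.05. Their camera results were, for interstitium, median 0.14, camera adjusted p = 0.00648, adjusted p = 0.465 with an estimated correlation, for adrenal cortex, median 0.29, camera adjusted p = 0.0283, adjusted p = 0.488 with an estimated correlation, for chromaffin cells, median 0.23, camera adjusted p = 0.0204, adjusted p = 0.488 with an estimated correlation, for cholesterol synthesis, median 0.24, camera adjusted p = 0.0204, adjusted p = 0.488 with an estimated correlation, and for germ cells, median 0.39, camera adjusted p = 0.0204, adjusted p = 0.488 with an estimated correlation. Adjusted over the list alone, 0, 0, 1, 0 and 1 of these genes rose. Camera calls were lost (medians in parentheses) for the interstitial list without wild-type replicate 1 (0.0443) and knock-out replicate 2 (0.0918), the adrenal cortex list without wild-type replicate 1 (0.0588) and knock-out replicate 2 (0.0648), the chromaffin list without wild-type replicate 1 (0.14), wild-type replicate 2 (0.23) and knock-out replicate 2 (0.0942), the cholesterol synthesis list without wild-type replicate 1 (0.00995) and knock-out replicate 2 (0.11), the germ cell list without wild-type replicate 1 (0.000787) and knock-out replicate 1 (0.027) and the male germ cell list without wild-type replicate 1 (-0.098). The Sertoli, fetal Leydig and meiosis lists did not pass, with medians of -0.45, -0.0472 and -0.0229 and camera adjusted p of 0.0721, 0.868 and 0.244. The direction of the test was up for the fetal Leydig list, whose mean was -0.0741, and for the meiosis list, whose mean was 0.0783. Among these, a camera call arose for the Sertoli list without wild-type replicate 1 (-0.49), the fetal Leydig list without wild-type replicate 1 (-0.86) and wild-type replicate 2 (1.43) and the meiosis list without wild-type replicate 1 (0.64) and wild-type replicate 2 (-0.52). Wild-type replicate 2 held 19% testis RNA, and the steroid hydroxylase gene Cyp17a1 read 18.3 and 32.5 against 6.58 and 1459 there (knock-out against wild type). The fold moved by over 1.5 times for Thbd (2.54-fold without wild-type replicate 1 and 7.62-fold without wild-type replicate 2) and Rassf2 (2.33-fold without wild-type replicate 1 and 6.1-fold without wild-type replicate 2).

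In total 67 genes changed in the ovary at E14.5, 25 higher and 42 lower, and 708 had an unadjusted p under 0.05. The count was 38 without wild-type replicate 1, 119 without wild-type replicate 2, 25 without knock-out replicate 1 and 17 without knock-out replicate 2. It was 44 with the almost identical wild-type testis arrays averaged, 22 with the stricter filter, 5 with only the 4 arrays of the comparison, and 295 with the opposite-sex share as a covariate. Of 26 named genes past the threshold, 12, 5, 16 and 15 lost it without wild-type replicate 1, wild-type replicate 2, knock-out replicate 1 and knock-out replicate 2, in that order.

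The ovary comparisons of the 2 stages share no array, but come from 1 fit with a shared variance per gene. In both, 8 genes fell. They were Lgr5, Notum, Msx1, Dach2, Insyn2b and Osr2, and D630039A03Rik and Grik1, picked out after their values were seen. Thbd and Lefty2 rose in both. Genes of low variance pass at either stage more easily, so no chance value is given for the number of shared genes. Of the 13 genes that fell at E12.5, 13 had a negative log2 change at E14.5, and of the 23 that rose, 18 had a positive one. The test of a difference between the stages (limma interaction) found 0 genes, with 557 at an unadjusted p under 0.05. That count was 2 without wild-type E12.5 replicate 1, 1 without knock-out E12.5 replicate 1, 25 without knock-out E12.5 replicate 2, 2 without wild-type E14.5 replicate 1 and 8 without wild-type E14.5 replicate 2.

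**Figure D2:**
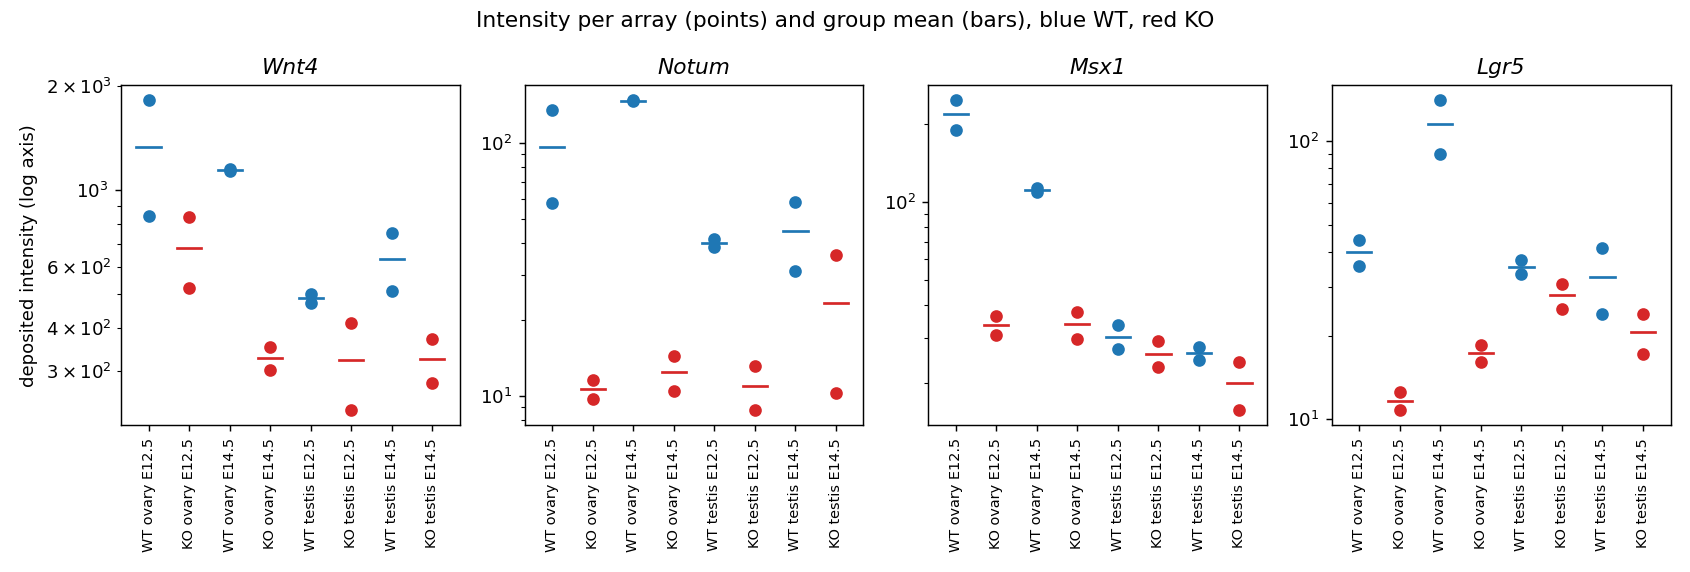
Deposited intensity (vertical axes, log scale) of Wnt4, Notum, Msx1 and Lgr5 in each of the 8 groups, with a point for each array, a bar for the group mean, blue for wild type and red for knock-out. Notum averaged 10.7 in knock-out and 96 in wild-type ovaries at E12.5, and 12.4 and 146 at E14.5.

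Whether knock-out gonads moved toward the other sex was tested with genes that differed at least 2-fold between wild-type testis and ovary at the other stage, so that lists and comparisons share no array. In the ovary at E12.5, 253 of 371 such genes lay toward the testis, with a median of 0.16 log2 (fry, two-sided, adjusted p = 0.339). In the ovary at E14.5 these were 43 of 67, with a median of 0.24 (adjusted p = 0.212). In the testis, medians toward the ovary were -0.20 at E12.5 and -0.11 at E14.5 (adjusted p = 0.425 for both). None of the 4 shifts passed the fry test, and at an unadjusted p under 0.05 their number was 0 as well. Under other settings a fry call arose for the ovary at E12.5 with a median of 0.24 without wild-type ovary E14.5 replicate 1. It arose for the ovary at E14.5 with a median of 0.53 with the opposite-sex share as a covariate, 0.18 with the 3'/5' ratio as a covariate, 0.64 with both as covariates, 0.58 with the almost identical arrays averaged, 0.43 without wild-type ovary E12.5 replicate 2 and 0.29 without wild-type testis E12.5 replicate 1. It arose for the testis at E14.5 with a median of -0.13 with the 3'/5' ratio as a covariate. With lists from the same stage, which share the wild-type arrays, medians were 0.32, 0.11, 0.45 and -0.11 for ovary E12.5, ovary E14.5, testis E12.5 and testis E14.5. Simulated unchanged knock-outs gave means of 0.18, 0.0982, 0.14 and 0.0955 for the same lists, and 28, 43, 10 and 83 of 100 draws lay at or above the observed medians. The central 95% of draws ran from -0.15 to 0.69 for the ovary and from -0.22 to 0.63 for the testis at E12.5. With lists of the other stage, simulated unchanged knock-outs gave fry p under 0.05 in 11, 7, 9 and 8 of 100 draws, so these p-values may be too small.

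**Figure D3:**
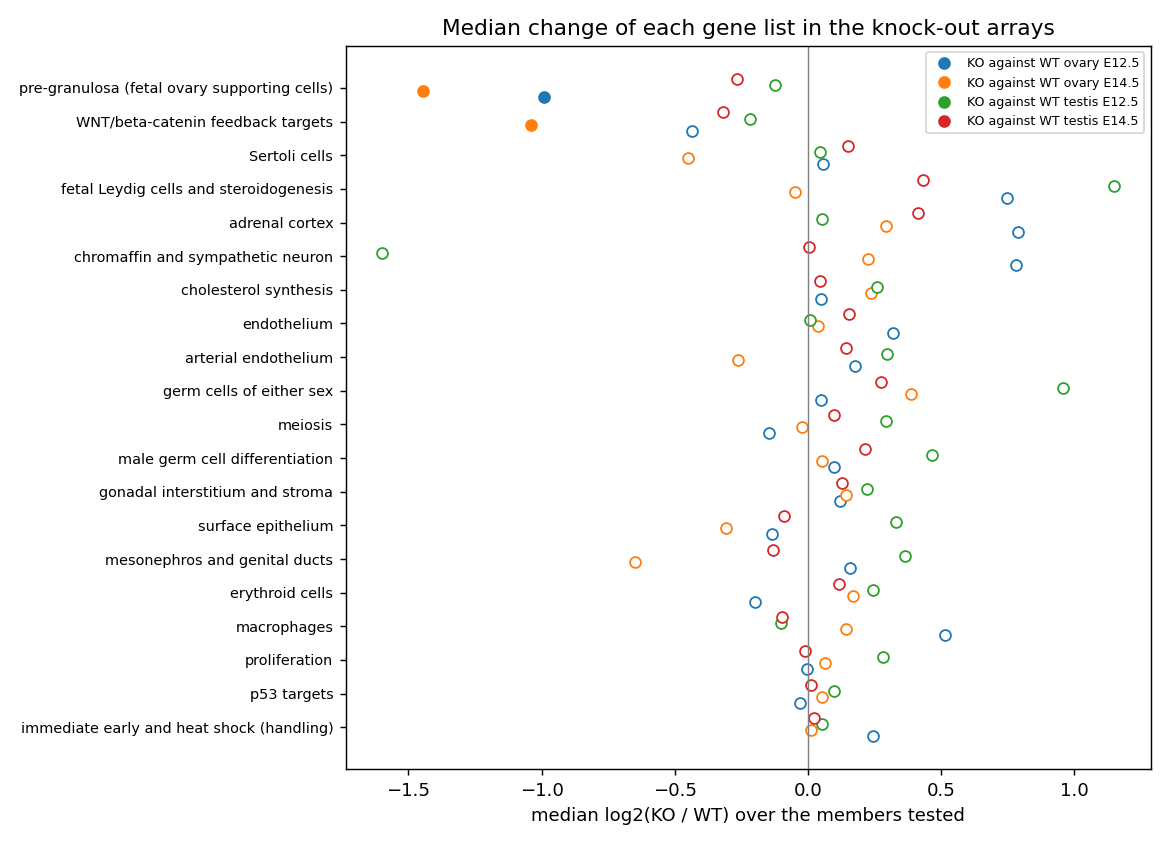
Median log2 change (horizontal axis, knock-out over wild type) of the measured members of each of the 20 gene lists, with a coloured point for each of the 4 knock-out comparisons, filled where the camera test passed both with the preset and with an estimated correlation and open otherwise. The pre-granulosa list lies at -0.99 in the E12.5 ovary and -1.44 in the E14.5 ovary.

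The testis comparison at E12.5 asked which genes differ between the arrays labelled Wnt4 knock-out and wild type in male gonads, and 5 genes changed. Htr1b rose from 28.8 ± 2.72 to 220.2 ± 115 (6.38-fold), the guanylate-binding protein gene Gbp2b rose 5.14-fold, Sec23ip rose 2.21-fold, and Zfpm2, a cofactor gene of GATA transcription factors, rose 1.87-fold. Miat, a long non-coding RNA, fell from 129 ± 8.54 to 22.2 ± 15 (5.56-fold). In the chromaffin and sympathetic neuron list 0 of 11 genes passed limma, with 10 at an unadjusted p under 0.05. In that list 10 fell when adjusted over the list alone (median -1.60, camera adjusted p = 1.58e-17, adjusted p = 0.0757 with an estimated correlation). Th, a member, read 7.39 ± 2.92 against 30.1 ± 0.0534 (adjusted p = 0.0612). In the germ cell, male germ cell and WNT feedback lists, 0 genes passed limma, 5, 4 and 2 had an unadjusted p under 0.05, and 3, 4 and 0 passed when adjusted over the list alone. Their camera results were, for germ cells, median 0.96, camera adjusted p = 0.00184, adjusted p = 0.62 with an estimated correlation, for male germ cells, median 0.47, camera adjusted p = 0.0118, adjusted p = 0.62 with an estimated correlation, and for WNT feedback, median -0.22, camera adjusted p = 0.00929, adjusted p = 0.62 with an estimated correlation. Dazl, a germ cell RNA-binding protein gene, read 2215 ± 101 against 919.6 ± 38 (adjusted p = 0.0626). Camera calls were lost for the WNT feedback list without knock-out replicate 1 (-0.16) and the male germ cell list without knock-out replicate 2 (0.28). The fetal Leydig list did not pass, with 0 of 9 genes past limma, 1 at an unadjusted p under 0.05, 0 adjusted over the list alone, a median of 1.15 and camera adjusted p = 0.0779, and its median relative to wild type was 0.30 in knock-out replicate 1 and 1.65 in replicate 2. A call arose for the fetal Leydig list without knock-out replicate 1 (1.65), the cholesterol synthesis list without knock-out replicate 1 (0.41), the interstitial list without wild-type replicate 1 (0.21) and knock-out replicate 1 (0.31), the proliferation list without wild-type replicate 1 (0.29) and knock-out replicate 1 (0.34) and the endothelial list without knock-out replicate 2 (-0.12). The median change of all genes was 0.10 in this comparison, and list medians stand on top of that shift. A fold moved by over 1.5 times for Miat (8.53-fold without knock-out replicate 1 and 3.62-fold without knock-out replicate 2), and the chromaffin median moved as far, to -1.01 without knock-out replicate 2.

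Of the 5 genes in the testis at E12.5, 4 were higher and 1 lower, 1365 genes had an unadjusted p under 0.05, and quantile normalization gave 2 higher and 1 lower. The limma count was 0 without wild-type replicate 1, 0 without wild-type replicate 2, 29 without knock-out replicate 1 and 0 without knock-out replicate 2, 0 with the almost identical wild-type arrays averaged, 1 with the stricter filter, 1 with only the 4 arrays of the comparison, and up to 365 with array weights. Each of the named calls was lost without wild-type replicate 1, wild-type replicate 2 or knock-out replicate 2.

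In the testis at E14.5, 1 gene changed by limma, with 183 at an unadjusted p under 0.05. Galnt5, a glycosyltransferase gene, fell from 50.9 ± 2.69 to 8.3 ± 3.63 (4.56-fold, log2 change -2.19, SE 0.183, adjusted p = 0.000206). No member of the 20 lists passed limma here. The WNT feedback list (median -0.32, camera adjusted p = 8.84e-08, adjusted p = 0.206 with an estimated correlation) and the pre-granulosa list (median -0.27, camera adjusted p = 0.00181, adjusted p = 0.292 with an estimated correlation) lay lower in the arrays labelled knock-out. The fetal Leydig (median 0.43, camera adjusted p = 0.00669, adjusted p = 0.737 with an estimated correlation), adrenal cortex (median 0.41, camera adjusted p = 0.0012, adjusted p = 0.292 with an estimated correlation) and male germ cell lists (median 0.21, camera adjusted p = 0.000547, adjusted p = 0.292 with an estimated correlation) lay higher. At an unadjusted p under 0.05 there were 2, 0, 1, 3 and 1 genes in the WNT feedback, pre-granulosa, fetal Leydig, adrenal cortex and male germ cell lists. Adjusted over the list alone, 0, 0, 0, 0 and 1 genes of these lists passed. Camera calls were lost (medians in parentheses) for the WNT feedback list without knock-out replicate 1 (-0.11), the pre-granulosa list without wild-type replicate 2 (-0.13) and knock-out replicate 1 (-0.0429), the fetal Leydig list without wild-type replicate 2 (0.32) and knock-out replicate 1 (0.27), the adrenal cortex list without knock-out replicate 1 (0.23) and the male germ cell list without wild-type replicate 1 (0.14) and knock-out replicate 2 (0.0955). Ovary RNA was 22.8% in wild-type replicate 2 and 16.5% in knock-out replicate 2. The gene count was 4 without wild-type replicate 2, 10 without knock-out replicate 1 and 3 without knock-out replicate 2. It was 0 with the stricter filter, under which Galnt5 was not tested, and 0 with only the 4 arrays of the comparison.

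The difference between arrays labelled knock-out and wild type was compared between the sexes by the interaction test of limma. At E12.5 it varied for 14 genes, 11 with a higher and 3 with a lower change in the ovary. Th differed by 3.92 log2 (SE 0.367, adjusted p = 0.000814), from 2.32 in the ovary and -1.60 in the testis. Msx1 changed by -2.55 in the ovary and -0.19, which did not pass, in the testis. In the chromaffin and sympathetic neuron list 2 of 11 genes differed, 10 when adjusted over the list alone (median 2.82, camera adjusted p = 4.03e-25, adjusted p = 0.0257 with an estimated correlation). That list's median also lay 0.70 higher in wild-type testis than ovary. Whether uneven tissue dissected along contributed was not tested. At E14.5, 0 genes differed by limma, with 295 at an unadjusted p under 0.05. The E12.5 count was 32 without wild-type ovary replicate 1, 2 without wild-type ovary replicate 2, 73 without knock-out ovary replicate 2, 1 without wild-type testis replicate 1, 1 without wild-type testis replicate 2 and 1 without knock-out testis replicate 2, 1 with the almost identical wild-type testis arrays averaged, 0 with the stricter filter and 0 with only the arrays of the contrast. The E14.5 count was 1 without wild-type ovary replicate 1, 16 without wild-type ovary replicate 2, 1 without wild-type testis replicate 1, 7 without knock-out testis replicate 1 and 1 without knock-out testis replicate 2.

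Wild-type gonads were then compared between the sexes. At E12.5 the Sertoli cell genes Cbln4 and Gdnf, a neurotrophic factor gene, were 4.88-fold and 3.45-fold higher in testis, and the vanin gene Vnn1 was 4.75-fold higher (517 ± 16.7 against 106 ± 20.4, testis against ovary). Fst was 9.85-fold lower (69.8 ± 0.393 against 724 ± 50.6), and Irx3 (9.51-fold), Msx1 (6.44-fold), Phlda2 (10.8-fold) and Sprr2d (22-fold) were lower as well. Of 20 Sertoli genes 4 were higher, 9 when adjusted over the list alone (median 1.23, camera adjusted p = 4.42e-13, adjusted p = 0.0459 with an estimated correlation). Of 15 pre-granulosa genes 5 were lower, 11 when adjusted over the list alone (median -1.32, camera adjusted p = 3.68e-10, adjusted p = 0.0459 with an estimated correlation). Of 9 surface epithelium genes 1, the LIM homeobox gene Lhx9 (2.0-fold), was lower, 6 when adjusted over the list alone (median -0.68, camera adjusted p = 0.00316, adjusted p = 0.215 with an estimated correlation). Of 8 mesonephros genes 1, the cadherin gene Cdh16, was lower, 5 when adjusted over the list alone (median -0.79, camera adjusted p = 0.00165, adjusted p = 0.235 with an estimated correlation). Among 8 male germ cell genes 2, Lefty2 and the Nodal co-receptor gene Tdgf1, were higher, 3 when adjusted over the list alone (median 0.15, camera adjusted p = 0.00165, adjusted p = 0.235 with an estimated correlation). No WNT feedback or chromaffin gene passed limma, 6 and 5 had an unadjusted p under 0.05, and 4 and 0 passed when adjusted over the list alone. Camera gave, for WNT feedback, median -0.59, camera adjusted p = 0.0361, adjusted p = 0.555 with an estimated correlation, and for chromaffin cells, median 0.70, camera adjusted p = 3.49e-05, adjusted p = 0.241 with an estimated correlation. The call was lost for the WNT feedback list without ovary replicate 1 (-0.54). The wild-type ovary arrays held 21.7% and 7.97% testis RNA, and ovary replicate 2 had a 3'/5' ratio of 1.76.

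In total 75 genes differed between the sexes at E12.5, 19 higher and 56 lower in testis, against a median of all genes of -0.11, and 2060 had an unadjusted p under 0.05. The count was 1565 without ovary replicate 1, 19 without ovary replicate 2, 11 without testis replicate 1 and 10 without testis replicate 2, 12 with the almost identical testis arrays averaged, and 2059 with the opposite-sex share as a covariate. Of 25 named genes past the threshold, 0, 15, 17 and 17 lost it without ovary replicate 1, ovary replicate 2, testis replicate 1 and testis replicate 2, in that order.

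At E14.5 meiotic genes were lower in testis than in ovary. Stra8, the retinoic acid target required for entry into meiosis, was 22.2-fold lower (54.5 ± 69.3 against 717 ± 157), and the meiotic recombinase gene Dmc1 was 17.4-fold lower. Of 20 meiosis genes 11 were lower, 19 when adjusted over the list alone (median -2.07, camera adjusted p = 6.38e-21, adjusted p = 0.0329 with an estimated correlation). Foxl2, a transcription factor gene of granulosa cells, was 13.7-fold lower, and 11 of 15 pre-granulosa genes were lower, 13 when adjusted over the list alone (median -1.94, camera adjusted p = 4.64e-17, adjusted p = 0.0135 with an estimated correlation). Of 20 Sertoli genes 10 were higher, 17 when adjusted over the list alone (median 2.05, camera adjusted p = 2.23e-16, adjusted p = 0.0255 with an estimated correlation), among them the androgenic dehydrogenase gene Hsd17b3 (9.18-fold). The ligand gene Dhh was 12.1-fold higher. Ovary replicate 2 held 19% testis RNA and testis replicate 2 held 22.8% ovary RNA. Values moved by over 1.5 times for Stra8 (6.62-fold without testis replicate 1 and 74.6-fold without testis replicate 2), Dmc1 (11.2-fold without ovary replicate 1 and 27.1-fold without ovary replicate 2) and Foxl2 (8.92-fold without ovary replicate 1 and 20.9-fold without ovary replicate 2). They did so too for Hsd17b3 (4.27-fold without ovary replicate 1 and 19.7-fold without ovary replicate 2) and Dhh (3.91-fold without ovary replicate 1 and 37.7-fold without ovary replicate 2). Medians moved as far for the meiosis list (-1.41 without ovary replicate 1, -2.71 without ovary replicate 2, -1.19 without testis replicate 1 and -2.90 without testis replicate 2) and the Sertoli list (1.43 without ovary replicate 1 and 2.75 without ovary replicate 2).

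Star, which encodes the protein that delivers cholesterol for steroid synthesis, was 12.7-fold higher in testis at E14.5 (536 ± 44.6 against 92.1 ± 122). Of 9 fetal Leydig genes 6 were higher, 9 when adjusted over the list alone (median 2.74, camera adjusted p = 1.01e-10, adjusted p = 0.0762 with an estimated correlation). Of 13 cholesterol synthesis genes 9 were higher, among them Dhcr7 (3.74-fold). For cholesterol genes this was 11 adjusted over the list alone (median 0.95, camera adjusted p = 2.44e-13, adjusted p = 0.0323 with an estimated correlation). Of 8 male germ cell genes 4 were higher, among them the piRNA pathway gene Piwil4 (11.8-fold). For male germ cell genes this was 8 adjusted over the list alone (median 1.04, camera adjusted p = 3.75e-10, adjusted p = 0.0255 with an estimated correlation). Of 14 genes of germ cells of either sex 5 were higher, among them the pluripotency gene Sox2 (10.9-fold). For germ cell genes this was 8 adjusted over the list alone (median 2.34, camera adjusted p = 3.07e-07, adjusted p = 0.119 with an estimated correlation). Of 15 WNT feedback genes 1 was higher (Wif1, 5.08-fold) and 2 were lower (Tnfrsf19 and Lgr5). For WNT feedback genes, 1 was higher and 6 were lower adjusted over the list alone (median -0.57, camera adjusted p = 0.0034, adjusted p = 0.243 with an estimated correlation). The heat shock genes Hspa1a (3.8-fold) and Hspa1b (3.69-fold) were the 2 members past limma of the immediate early and heat shock list (median 0.24, camera adjusted p = 0.0331, adjusted p = 0.333 with an estimated correlation), and 2 passed adjusted over the list alone. A camera call was lost for the immediate early list without ovary replicate 1 (-0.0302) and testis replicate 1 (0.0835). Ovary replicate 2 held 19% testis RNA and stood apart from replicate 1, with Star at 568 and 505 against 5.83 and 178 (testis against ovary). The fold changed by over 1.5 times for Star (2.96-fold without ovary replicate 1 and 54.8-fold without ovary replicate 2), Sox2 (3.6-fold without ovary replicate 1 and 33.2-fold without ovary replicate 2) and Piwil4 (23.3-fold without testis replicate 1 and 6.03-fold without testis replicate 2), and testis replicate 2 held 22.8% ovary RNA. The median did so for the fetal Leydig list (1.21 without ovary replicate 1 and 3.80 without ovary replicate 2) and the germ cell list (0.87 without ovary replicate 1 and 3.02 without ovary replicate 2).

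In total 473 genes differed between the sexes at E14.5, 279 higher and 194 lower in testis, and 1961 had an unadjusted p under 0.05. The count was 87 without ovary replicate 1, 913 without ovary replicate 2, 170 without testis replicate 1 and 196 without testis replicate 2, 1082 with the opposite-sex share as a covariate and 0 with only the 4 arrays of the comparison. Of 56 named genes past the threshold, 33, 2, 27 and 26 lost it without ovary replicate 1, ovary replicate 2, testis replicate 1 and testis replicate 2, in that order.

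Between E12.5 and E14.5 the wild-type ovary gained meiotic transcripts. Stra8 rose from 9.82 ± 4.05 to 717 ± 157 (52.7-fold), the synaptonemal complex gene Sycp1 rose 59.4-fold, and 19 of 20 meiosis genes rose, 19 when adjusted over the list alone (median 3.33, camera adjusted p = 8.13e-32, adjusted p = 0.0625 with an estimated correlation). Foxl2 rose 6.0-fold, and of 15 pre-granulosa genes 4 rose, while adjusted over the list alone 4 rose and 2 fell (median 0.16, camera adjusted p = 0.0369, adjusted p = 0.467 with an estimated correlation). Chgb, a chromogranin gene of neuroendocrine cells, fell from 847 ± 42.3 to 7.33 ± 2.09 (75.8-fold), and 8 of 11 chromaffin genes fell, 8 when adjusted over the list alone (median -2.01, camera adjusted p = 9.43e-11, adjusted p = 0.114 with an estimated correlation). Whether these transcripts came from the gonad or from tissue dissected along at E12.5 was not tested. The embryonic haemoglobin gene Hbb-bh1 fell 19.4-fold, and 4 of 9 erythroid genes fell, 7 when adjusted over the list alone (median -1.0, camera adjusted p = 4.59e-07, adjusted p = 0.114 with an estimated correlation). Of 8 mesonephros genes 3 fell, among them the receptor gene Ret (4.13-fold). For mesonephros genes this was 3 adjusted over the list alone (median -0.62, camera adjusted p = 0.0278, adjusted p = 0.467 with an estimated correlation). In the germ cell list 4 genes rose, among them Mael (14.9-fold), and 3 fell, among them Sox2 (9.28-fold). That list did not pass camera, with a median of -1.02, a mean of -0.30, an upward direction of the test and adjusted p = 0.803. Camera calls were lost for the pre-granulosa list without E12.5 replicate 1 (0.21) and E14.5 replicate 1 (0.046) and the mesonephros list without E12.5 replicate 2 (-0.17) and arose for the germ cell list without E14.5 replicate 1 (0.45) and E14.5 replicate 2 (-1.77). E14.5 replicate 2 held 19% testis RNA, and folds changed by over 1.5 times for Sycp1 (33.7-fold without E14.5 replicate 1 and 105-fold without E14.5 replicate 2), Foxl2 (3.92-fold without E14.5 replicate 1 and 9.18-fold without E14.5 replicate 2) and Sox2 (3.05-fold without E14.5 replicate 1 and 28.2-fold without E14.5 replicate 2). The median moved as far for the meiosis list (4.22 without E14.5 replicate 2) and the chromaffin list (-1.28 without E12.5 replicate 1).

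In total 538 genes changed in the wild-type ovary between the stages, 309 higher and 229 lower at E14.5, and 2270 had an unadjusted p under 0.05. The count was 1258 without E12.5 replicate 1, 271 without E12.5 replicate 2 and 210 without E14.5 replicate 1, 116 with only the 4 arrays of the comparison, 192 with array weights and 1122 with the opposite-sex share as a covariate. Of 47 named genes past the threshold, 1, 10, 16 and 4 lost it without E12.5 replicate 1, E12.5 replicate 2, E14.5 replicate 1 and E14.5 replicate 2, in that order.

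In the wild-type testis, steroidogenic genes rose between the stages. Cyp17a1, a steroid hydroxylase gene, rose from 15.6 ± 0.418 to 3319 ± 662 (168-fold), and Cyp11a1, which encodes the first enzyme of steroid synthesis, rose 41.3-fold. Of 9 fetal Leydig genes 8 rose, 9 when adjusted over the list alone (median 2.01, camera adjusted p = 1.05e-06, adjusted p = 0.341 with an estimated correlation), and of 13 cholesterol synthesis genes 11 rose, 12 when adjusted over the list alone (median 1.18, camera adjusted p = 3.16e-09, adjusted p = 0.106 with an estimated correlation). Of 14 interstitial genes 9 rose, among them the collagen gene Col1a1 (3.2-fold) and the smooth muscle actin gene Acta2 (3.01-fold). For interstitial genes this was 11 adjusted over the list alone (median 0.74, camera adjusted p = 7.8e-08, adjusted p = 0.106 with an estimated correlation). In the germ cell list 7 genes rose, among them Mael (25.1-fold), and 1 fell. For germ cell genes, 8 rose and 2 fell adjusted over the list alone (median 1.67, camera adjusted p = 6.76e-05, adjusted p = 0.344 with an estimated correlation). Of 20 meiosis genes 6 rose, 9 when adjusted over the list alone (median 1.01, camera adjusted p = 2.78e-05, adjusted p = 0.394 with an estimated correlation). Chgb fell 100.4-fold, and 10 of 11 chromaffin genes fell, 10 when adjusted over the list alone (median -2.44, camera adjusted p = 2.01e-13, adjusted p = 0.106 with an estimated correlation). Of 9 erythroid genes 3 fell, 4 when adjusted over the list alone (median -0.77, camera adjusted p = 0.00268, adjusted p = 0.344 with an estimated correlation), a call lost for the erythroid list without E14.5 replicate 1 (-0.46). Hspa1a (8.6-fold) and Hspa1b (8.63-fold) rose in the immediate early and heat shock list (median 0.41, camera adjusted p = 0.00773, adjusted p = 0.369 with an estimated correlation), with 2 when adjusted over the list alone. E14.5 replicate 2 held 22.8% ovary RNA, and the median of the meiosis list was 0.45 without that array and 1.24 without replicate 1.

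In total 1306 genes changed in the wild-type testis between the stages, 830 higher and 476 lower at E14.5, and 3269 had an unadjusted p under 0.05. The count was 339 without E12.5 replicate 1, 260 without E12.5 replicate 2, 741 without E14.5 replicate 1 and 425 without E14.5 replicate 2, 302 with the almost identical E12.5 arrays averaged, and up to 3940 with array weights. Of 64 named genes past the threshold, 18, 19, 12 and 15 lost it without E12.5 replicate 1, E12.5 replicate 2, E14.5 replicate 1 and E14.5 replicate 2, in that order. In the testis the difference between arrays labelled knock-out and wild type varied between the stages for 1 gene, Galnt5 (limma interaction, difference -2.30, adjusted p = 0.00699), and that count was 0 without wild-type E12.5 replicate 1, 0 without wild-type E12.5 replicate 2, 5 without knock-out E12.5 replicate 1, 0 without knock-out E12.5 replicate 2, 0 without wild-type E14.5 replicate 2, 7 without knock-out E14.5 replicate 1 and 2 without knock-out E14.5 replicate 2. It was 0 with the almost identical E12.5 arrays averaged, 0 with the stricter filter, under which Galnt5 was not tested, and 0 with only the arrays of the contrast.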

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

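The tests of explanations given here were chosen after the results were seen, apart from the test of the 3'/5' ratio on the steroidogenic list. Each group held 2 arrays, so outlying arrays within a group were not tested.

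At E12.5 the difference between arrays labelled knock-out and wild type varied between ovary and testis for 14 genes by the limma interaction test, and in the testis it varied between the stages for 1 gene. The difference of log2 changes, ovary minus testis, was 4.22 for the sodium channel gene Scn3b, 4.21 for Rgs4, 4.2 for Stmn3, 3.92 for Th, 3.78 for Dbh, which encodes the enzyme that makes noradrenaline, and 3.31 for Miat. It was -2.36 for Msx1 and -3.28 for Phlda2. Genes picked out after their values were seen were Actc1 (5.22), A930009L07Rik (4.61), Tbx20 (3.48), Disp2 (2.25), Celsr3 (1.17) and Cfap161 (-2.14). Tissue dissected along was not tested as a cause. For Galnt5 in the testis the difference, E14.5 minus E12.5, was -2.3. With the almost identical wild-type testis arrays averaged, the counts were 1 between the sexes and 0 between the stages.

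Control probe sets enter no comparison. Both knock-out arrays lay above both wild-type arrays in 11 of 64 pairings of a control probe set with a comparison, where chance gives 16.7%, or 10.7. In the testis at E12.5 the ratio of means, knock-out over wild type, was 22.6 for the 3' set of 18S ribosomal RNA, 11.3 for its middle set and 8.9 for its 5' set. The 3' set read 1113 and 644 in knock-out against 42 and 35.7 in wild-type arrays, but over all arrays it ran from 20.4 to 3776, with 53.9 and 2545 inside the wild-type ovary group at E14.5. In the ovary at E12.5 the ratio was 1.1 for actin (3') and 1.43 for pyruvate carboxylase (3'). In the ovary at E14.5 it was 1.17, 1.69 and 1.17 for the 3', middle and 5' sets of pyruvate carboxylase, and 1.32 and 1.39 for the 3' and middle sets of the transferrin receptor. In the testis at E14.5 it was 1.2 for pyruvate carboxylase (3').

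Some ovary arrays held Y-linked transcripts. Exchanged sex labels would give an ovary array a testis share near 1, and the highest, 0.217, argues against this. Cross-hybridisation to X-linked copies would give each such a signal, and the lowest was -0.00544. For wild-type ovary E14.5 replicate 2, 14 autosomal Sertoli and Leydig genes at least 8-fold above replicate 1 in testis were used. Their median testis share was 0.282 (quartiles 17.8% and 32.5%, range 9.15% to 43.9%) beside 19% from the Y-linked genes. The 19% is below that median but within these quartiles, so both measures go with testis RNA in this array. Its exact share stays uncertain, and no route of entry or biological explanation was tested.

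Arrays of different E12.5 groups deviated together: on the first principal component of 7 samples, with the mean of the almost identical testis arrays as 1 (52.6% of the variance), wild-type ovary replicate 2 lay at 33.5 and knock-out ovary replicate 1 at 55.1. The Wnt4 genotype would part the ovary arrays, but the gap between the genotypes was -28.5, where a negative value means overlap. Short labelled RNA may contribute, as Pearson's r with the 3'/5' ratio was 0.809 (exact permutation p = 0.0236) and Spearman's rho 0.571 (exact permutation p = 0.20), both two-sided. Without the 2 samples farthest from the median ratio, knock-out ovary replicate 1 and knock-out testis replicate 1, r was 0.941 over 5 samples. The difference between both coefficients keeps this open, as does knock-out testis replicate 1, left out of that last value, which lay at -20.8 with a log2 ratio of 0.82.

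In the ovary arrays labelled knock-out at E12.5 the steroidogenic list had medians of 1.45 and 0.42 relative to wild type, with 0 of 9 genes past limma, 5 at an unadjusted p under 0.05, and adjusted p = 0.41 with an estimated correlation. Testis RNA would need a higher Y-linked share in the knock-out arrays, and the difference of mean shares was -0.055. The 3'/5' ratio as a covariate lowered the list's median by 0.0312, from 0.75 to 0.72, which argues against short RNA as the whole cause. Adrenal or sympathetic tissue dissected along may contribute: the chromaffin list's median lay above wild type in both arrays, by at least 0.771, but with adjusted p = 0.168 with an estimated correlation and a camera call lost for the chromaffin list without wild-type replicate 2 (0.61), and Chga, a chromogranin gene, read 329 and 85.3 against 45.4 and 36.4 (knock-out against wild type, limma adjusted p = 0.106). An effect of the Wnt4 genotype on steroidogenic cells stays open as untested.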

How the results depend on the processing

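Covariates, averaged arrays, arrays left out together and the crossed pairing were chosen after seeing the data. Counts of genes are compared here. With a 4-fold pseudocount counts were 9 (knock-out testis E12.5), 3 (knock-out testis E14.5) and 2 (genotype by sex E14.5). Without the filter counts were 12 (knock-out testis E12.5). With the stricter filter, which tests fewer genes, counts were 7 (knock-out ovary E12.5), 22 (knock-out ovary E14.5), 1 (knock-out testis E12.5), 0 (knock-out testis E14.5), 49 (sex E12.5), 268 (sex E14.5), 0 (genotype by sex E12.5) and 0 (genotype by stage in testis). With quantile normalization counts were 3 (knock-out testis E12.5). Without the intensity trend counts were 22 (knock-out ovary E12.5), 1 (knock-out testis E12.5) and 3 (genotype by sex E12.5). With robust moderation counts were 3 (knock-out testis E12.5). With only the arrays of the contrast counts were 0 (knock-out ovary E12.5), 5 (knock-out ovary E14.5), 1 (knock-out testis E12.5), 0 (knock-out testis E14.5), 13 (sex E12.5), 0 (sex E14.5), 116 (ovary stages), 3365 (testis stages), 0 (genotype by sex E12.5) and 0 (genotype by stage in testis). With array weights counts were 4 (knock-out ovary E12.5), 365 (knock-out testis E12.5), 192 (ovary stages), 3940 (testis stages), 5 (genotype by sex E14.5) and 3 (genotype by stage in testis). With the mean of probe sets counts were 1 (knock-out testis E12.5) and 47 (sex E12.5). With the opposite-sex share as covariate counts were 58 (knock-out ovary E12.5), 295 (knock-out ovary E14.5), 72 (knock-out testis E12.5), 2059 (sex E12.5), 1082 (sex E14.5), 1122 (ovary stages), 28 (genotype by sex E12.5) and 13 (genotype by sex E14.5). With the 3'/5' ratio as covariate counts were 8 (knock-out testis E12.5), 41 (sex E12.5) and 30 (genotype by sex E12.5). With both covariates counts were 254 (knock-out ovary E14.5), 43 (knock-out testis E12.5), 1176 (sex E14.5), 317 (ovary stages), 38 (genotype by sex E12.5), 11 (genotype by sex E14.5), 1 (genotype by stage in ovary) and 2 (genotype by stage in testis). With the almost identical arrays averaged counts were 9 (knock-out ovary E12.5), 44 (knock-out ovary E14.5), 0 (knock-out testis E12.5), 12 (sex E12.5), 302 (testis stages), 1 (genotype by sex E12.5) and 0 (genotype by stage in testis). Without the arrays of high 3'/5' ratio or opposite-sex RNA counts were 12 (knock-out ovary E12.5), 119 (knock-out ovary E14.5), 29 (knock-out testis E12.5), 2 (knock-out testis E14.5), 19 (sex E12.5), 425 (testis stages), 26 (genotype by sex E12.5), 6 (genotype by sex E14.5), 5 (genotype by stage in ovary) and 2 (genotype by stage in testis). At an adjusted p under 0.01 counts were 8 (knock-out ovary E12.5), 22 (knock-out ovary E14.5), 0 (knock-out testis E12.5), 25 (sex E12.5), 182 (sex E14.5), 215 (ovary stages), 469 (testis stages) and 1 (genotype by sex E12.5). With at least 2-fold change counts were 769 (testis stages). Some settings use fewer arrays or genes or added covariates, and beyond that the cause was not tested. Leaving out each array in turn, counts ranged from 16 to 203 (knock-out ovary E12.5), 17 to 119 (knock-out ovary E14.5), 0 to 29 (knock-out testis E12.5), 1 to 10 (knock-out testis E14.5), 10 to 1565 (sex E12.5), 87 to 913 (sex E14.5), 210 to 1258 (ovary stages), 260 to 741 (testis stages), 1 to 73 (genotype by sex E12.5), 0 to 16 (genotype by sex E14.5), 0 to 25 (genotype by stage in ovary) and 0 to 7 (genotype by stage in testis), where the lone array left in a group is assumed to vary like the other groups.

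Replicate numbers are shared between groups, but with 2 pairs a comparison they do not establish a pairing. The correlation of same-numbered deviations was -0.656, -0.186, -0.0316 and 0.581 for knock-out ovary E12.5, ovary E14.5, testis E12.5 and testis E14.5. With the replicate number as a block the counts were 27 (knock-out ovary E12.5), 56 (knock-out ovary E14.5), 21 (knock-out testis E12.5), 1 (knock-out testis E14.5), 61 (sex E12.5), 479 (sex E14.5), 494 (ovary stages), 1342 (testis stages), 14 (genotype by sex E12.5), 0 (genotype by sex E14.5), 0 (genotype by stage in ovary) and 1 (genotype by stage in testis). Crossing the numbers as a block gave 143 genes in the ovary at E12.5 and 71 at E14.5.

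Some shifts toward the other sex changed in call or direction. With the opposite-sex share, the 3'/5' ratio or both as covariates, knock-out ovary E14.5 gave 0.53, 0.18 and 0.64. It gave 0.58 with the almost identical arrays averaged, and knock-out testis E14.5 gave -0.13 with the 3'/5' ratio as covariate. With the list of the same stage, knock-out ovary E12.5 gave 0.32 and knock-out testis E12.5 gave 0.45. For these shifts the cause was not tested. Leaving out each array in turn, their medians ranged from 0.0951 to 0.24 (knock-out ovary E12.5), 0.0956 to 0.58 (knock-out ovary E14.5), -0.29 to -0.0109 (knock-out testis E12.5) and -0.29 to 0.0328 (knock-out testis E14.5). Fitting only the arrays of the contrast leaves no gene list for the shifts at E12.5, which were then not computed. The direction of the camera test, which is not always that of the median, turned for adrenal cortex in sex E14.5 (0.051 with the stricter filter), meiosis in knock-out ovary E14.5 (-0.48 with both covariates), germ cell in sex E12.5 (0.67 with both covariates), meiosis in knock-out ovary E14.5 (-0.52 without the arrays of high 3'/5' ratio or opposite-sex RNA), cholesterol synthesis in ovary stages (0.0351 without the arrays of high 3'/5' ratio or opposite-sex RNA), germ cell in ovary stages (-1.83 without the arrays of high 3'/5' ratio or opposite-sex RNA), fetal Leydig in knock-out ovary E14.5 (-0.86 without wild-type replicate 1), germ cell in knock-out ovary E14.5 (0.000787 without wild-type replicate 1), meiosis in knock-out ovary E14.5 (-0.52 without wild-type replicate 2), germ cell in ovary stages (-1.77 without E14.5 replicate 2) and meiosis in knock-out testis E14.5 (-0.31 without wild-type replicate 1), where the value is the median under that setting. Top2a in testis stages turned to -0.45 with the mean of probe sets. Among lists past camera with or without the setting, medians changed sign without a turn of the test for mesonephros in sex E14.5 (-0.36 with the mean of probe sets, from 0.0575), erythroid in sex E14.5 (-0.18 with the opposite-sex share as covariate, from 0.40), fetal Leydig in knock-out ovary E14.5 (0.35 with both covariates, from -0.0472), erythroid in sex E14.5 (-0.14 with both covariates, from 0.40), fetal Leydig in knock-out ovary E14.5 (1.43 without the arrays of high 3'/5' ratio or opposite-sex RNA, from -0.0472), endothelial in knock-out testis E12.5 (-0.12 without knock-out replicate 2, from 0.00999), meiosis in knock-out ovary E14.5 (0.64 without wild-type replicate 1, from -0.0229), male germ cell in knock-out ovary E14.5 (-0.098 without wild-type replicate 1, from 0.0536), mesonephros in sex E14.5 (-0.12 without ovary replicate 1, from 0.0575), immediate early in sex E14.5 (-0.0302 without ovary replicate 1, from 0.24), germ cell in ovary stages (0.45 without E14.5 replicate 1, from -1.02) and fetal Leydig in knock-out ovary E14.5 (1.43 without wild-type replicate 2, from -0.0472). For these turns the cause was not tested. Over the arrays left out in turn, medians of the lists whose test turned ranged from -0.86 to 1.43 (fetal Leydig, knock-out ovary E14.5), 0.000787 to 0.63 (germ cell, knock-out ovary E14.5), -1.77 to 0.45 (germ cell, ovary stages), -0.52 to 0.64 (meiosis, knock-out ovary E14.5) and -0.31 to 0.46 (meiosis, knock-out testis E14.5). Named genes past the threshold kept their call in 302 of 459 (knock-out ovary E12.5), 433 of 540 (knock-out ovary E14.5), 63 of 105 (knock-out testis E12.5), 19 of 20 (knock-out testis E14.5), 353 of 520 (sex E12.5), 989 of 1167 (sex E14.5), 891 of 983 (ovary stages) and 1211 of 1338 (testis stages) alternative values. Low intensities limit these comparisons, as the median intensity of an array lay between 9.32 and 10.5 and the pseudocount was 4.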

Other observations

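All results in this part come from tests planned with the lists.

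Markers of other cell types were compared between wild-type gonads. At E14.5, 3 of 9 surface epithelium genes were lower in testis, the uroplakin gene Upk1b (2.74-fold), the keratin gene Krt19 (2.32-fold) and the homeobox gene Emx2 (2.24-fold). For surface epithelium genes this was 5 adjusted over the list alone (median -0.55, camera adjusted p = 4.35e-05, adjusted p = 0.0329 with an estimated correlation). Of 14 interstitial genes 2 were higher in testis, the hedgehog receptor gene Ptch1 (2.44-fold) and Acta2 (2.06-fold). For interstitial genes this was 3 adjusted over the list alone (median 0.39, camera adjusted p = 0.00614, adjusted p = 0.274 with an estimated correlation). In the adrenal cortex, erythroid and macrophage lists 0 genes passed limma at that stage, 4, 2 and 3 had an unadjusted p under 0.05, and 1, 0 and 0 passed adjusted over the list alone. There camera gave, for adrenal cortex, median 0.54, camera adjusted p = 0.029, adjusted p = 0.333 with an estimated correlation, for erythroid cells, median 0.40, camera adjusted p = 0.029, adjusted p = 0.333 with an estimated correlation, and for macrophages, median -0.40, camera adjusted p = 0.0197, adjusted p = 0.333 with an estimated correlation. The calls were lost (medians in parentheses) for the adrenal cortex list without ovary replicate 1 (0.36) and testis replicate 1 (0.53), the erythroid list without ovary replicate 1 (0.30), ovary replicate 2 (0.39) and testis replicate 2 (0.16) and the macrophage list without ovary replicate 1 (-0.23) and testis replicate 2 (-0.36). The mesonephros list did not pass there, with a median of 0.0575, a mean of -0.60, a downward direction of the test and camera adjusted p = 0.0823, while its members Calb1 (19.3-fold) and Pax8 (1.67-fold) were lower in testis. A camera call arose for the mesonephros list without ovary replicate 1 (-0.12) and testis replicate 1 (0.16), and the fold moved by over 1.5 times for Calb1 (34.3-fold without testis replicate 1 and 10.8-fold without testis replicate 2).

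In the wild-type ovary between the stages, the matrix genes Lum (3.62-fold) and Dcn (3.09-fold) rose in the interstitial list (median 0.12, camera adjusted p = 0.0269, adjusted p = 0.467 with an estimated correlation), and Mc2r, the adrenocorticotropin receptor gene, fell 4.2-fold in the adrenal cortex list (median -0.51, camera adjusted p = 0.0334, adjusted p = 0.467 with an estimated correlation). Camera gave, for arterial endothelium, median -0.30, camera adjusted p = 0.0304, adjusted p = 0.467 with an estimated correlation, for macrophages, median 0.34, camera adjusted p = 0.0304, adjusted p = 0.487 with an estimated correlation, and for cholesterol synthesis, median 0.23, camera adjusted p = 0.0334, adjusted p = 0.487 with an estimated correlation, with 0 genes of each past limma. At an unadjusted p under 0.05 these lists held 3, 3 and 1 genes, and 2, 1 and 0 passed adjusted over the list alone. Camera calls were lost (medians in parentheses) for the interstitial list without E12.5 replicate 1 (0.0218) and E14.5 replicate 2 (0.12), the adrenal cortex list without E12.5 replicate 1 (-0.66), E12.5 replicate 2 (-0.33) and E14.5 replicate 1 (-0.27), the arterial list without E12.5 replicate 1 (-0.49), E12.5 replicate 2 (-0.20) and E14.5 replicate 2 (-0.27), the macrophage list without E12.5 replicate 1 (0.14) and E14.5 replicate 1 (0.14) and the cholesterol synthesis list without E12.5 replicate 2 (0.18) and E14.5 replicate 2 (0.0879). The WNT feedback list had Nkd2 (3.13-fold) and Lgr5 (2.66-fold) higher and the cyclin gene Ccnd1 (1.68-fold) lower, with a median of -0.0541, a mean of 0.21, an upward direction of the test and camera adjusted p = 0.369.

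In the ovary arrays labelled knock-out at E12.5, no member of the Sertoli, proliferation, p53 or arterial lists passed limma, 2, 0, 0 and 2 had an unadjusted p under 0.05, and 1, 0, 0 and 2 passed adjusted over the list alone. Camera adjusted p was 0.531 for Sertoli (median 0.0584, mean -0.15, test downward), 0.489 for proliferation (median -0.00324), 0.525 for p53 targets (median -0.0297) and 0.353 for arterial endothelium (median 0.18). In the wild-type testis between the stages the pre-granulosa list had a median of 0.29, a mean of 0.0649, a downward direction of the test and camera adjusted p = 0.757, with Nr0b1 (2.35-fold) and Kctd14 (1.73-fold) lower.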
